A study of Mus musculus with 32 samples.

How the data were processed

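Liver RNA of 32 male mice of the B6C3F1 hybrid strain was measured on Affymetrix MG-U74Av2 arrays, 1 array per mouse and 4 arrays in each of 8 groups, per the labels. The control group (CON) received 93 kcal per week of a defined diet. The long-term calorie restricted group (LTCR) received 52.2 kcal per week from 5 months of age. The 8-week restricted group (CR8) was taken at 20 months to 77 kcal per week for 2 weeks and then to 52.2 kcal per week. The other groups received for 8 weeks from 20 months the control diet with metformin (MET), glipizide (GLIP), both drugs (GM), rosiglitazone (ROS) or a soy isoflavone extract (SOY). Doses were not given. All mice were killed at 22 months after a fast of 48 hours, and were housed singly from 5 months, per the labels' protocols.

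The deposited values were 1 linear intensity per probe set and array, between 0.1 and 47323.7, which the authors had already scaled. The source of that statement is the table itself: the mean of each column without the top and bottom 2% of its values lay between 500.4 and 500.5. The software, its version and its background correction were not given in the sources used here, and neither were detection calls, scan dates or batches. The table held 12488 probe sets, of which 66 were control probe sets and were left out of every test. Of the other 12422, the platform annotation gave 1 gene symbol for 10833, several for 396 and none for 1193; genes were named only from probe sets with 1 symbol. No symbol needed an update through its gene identifier, and 16 symbols without a match kept the platform's name.

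Intensities were analysed as log2(intensity + 27), the added value being the 20th percentile of all intensities. Such a scale understates the change of dim genes. Where all 4 arrays of 1 group lay below the added value, a gene was given a bound, the mean log2 intensity of the other group less the log2 of the added value, as no detection calls were at hand. Probe sets were kept where their mean over all arrays exceeded the 40th percentile of all intensities, 94.2, which left 7357 probe sets, 6592 of them with 1 symbol, for 5545 genes. A gene was represented by its probe set with the highest mean over the 32 arrays; of the tested probe sets, 5895 had the plain identifier suffix of a single transcript. Probe sets for near-identical copies, such as those of Hspa1b and Cyp4a12b, can take signal from both copies.

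Differences were tested with limma 3.58.1 in R 4.3.3 (lmFit, then eBayes with an intensity trend) in 1 fit over the 8 groups, with 24 residual and 4.59 prior degrees of freedom, so that all groups shared 1 estimate of the spread. The Benjamini-Hochberg threshold was 0.05 within each of 10 comparisons, which were the 7 groups against CON, LTCR against CR8, GM against MET and GM against GLIP. Errors of log2 changes are standard errors from this fit, and errors of intensities are SDs over 4 arrays. Of 39 gene lists for liver metabolism, stress, hormone responses and other cell types, 38 had at least 4 measured genes and were tested with limma's camera at a preset correlation of 0.01; the list of T and NK cell markers was too small. The same lists were run with an estimated correlation and with limma's fry. List means per array are means over genes of log2 values minus the CON mean, and single values were compared with two-sided exact permutation tests, for which 4 arrays against 4 allow no p below 0.0286.

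Because treatments and LTCR were set against the same CON arrays, their resemblance was measured as the covariance of log2 changes with the 4 CON arrays split in each of 6 ways, 2 arrays for LTCR and 2 for the treatment. Unchanged groups were simulated 100 times against shared controls. The error of the covariance is a jackknife over the 4 treated arrays. The LTCR score of an array is the mean of the probe sets called higher in LTCR minus the mean of those called lower, relative to CON.

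The comparisons, lists, tests and rule for named genes were fixed before the data were examined. The rule took, for each comparison, the 10 genes with the largest rise and the 10 with the largest fall among those past the threshold whose arrays did not overlap between groups. It added the 4 members of each called list with the smallest p and, where fewer than 10 genes passed, the 6 genes with the smallest p. It let the text leave out the least informative, allowed a fixed set of metabolic genes in every comparison, and allowed genes named in one comparison to be given in others. After the alternatives had been computed, 13 optional gene results not past the threshold were for a time left out of the tables; all 13 were put back.

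Fixed alternatives were quantile normalization, scaling to equal medians, an added value of 1 or at the 40th percentile, no filter or a filter at the 60th percentile, a fit to the 2 groups compared, the replicate number as a block, 1 probe set per gene, probe sets of single transcripts alone, and each array left out in turn. Where several single arrays each ended a gene's call, the one giving the highest adjusted p is named. Chosen after the data had been seen were fits without 5 arrays high in muscle transcripts, without 3 arrays high in acute phase transcripts, and with SOY in place of CON. The tests were tried first on simulated data with LTCR against CON, 7357 probe sets and 20 simulations: 42.2% of probe sets changed by 0.5 on the log2 scale were called, 87.0% at 1, 96.2% at 1.5 and 98.7% at 2. Figures used matplotlib 3.10.9 under Python 3.11.15. Few arrays limit precision. Gene p-values rest on the spread between arrays of separate mice, preset camera's on that between genes.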

Results

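Liver transcripts were measured in 32 aged male mice to ask how far 4 candidate treatments and 1 combination resemble calorie restriction. The 8 groups of 4 mice were fed a control diet (CON), were calorie restricted for most of adult life (LTCR) or for 8 weeks (CR8), or received the control diet with metformin (MET), a biguanide that lowers blood glucose, glipizide (GLIP), a sulfonylurea that stimulates insulin release, both drugs (GM), rosiglitazone (ROS), an activator of the nuclear receptor PPAR gamma, or soy isoflavones (SOY). Array columns had medians between 144.8 and 170 intensity units. Arrays correlated between 0.928 and 0.977 over the tested probe sets, with a median of 0.968 within groups and 0.960 between groups. The column medians were 164 ± 1.33 in CON, 160 ± 1.37 in LTCR, 148 ± 4.48 in GM and 151 ± 2.09 in SOY (SD, n = 4). Each of these 3 groups lay wholly below CON (exact p = 0.0286, adjusted p = 0.0667), which missed the threshold after adjustment. Scaling all arrays to equal medians moved the median log2 change of all probe sets by up to 0.135, in GM from -0.05 to 0.09 against CON, so small changes depend on the scaling.

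**Figure D1:**
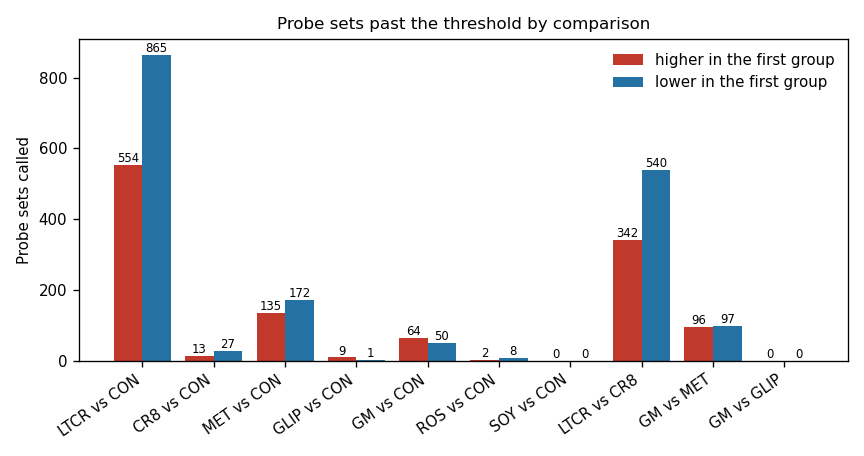
Bars give the number of probe sets (vertical axis) past the limma threshold in each of the 10 comparisons (horizontal axis), higher (red) or lower (blue) in the first group named, of 7357 tested.

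LTCR was compared with CON for the effect of long-term restriction. Interferon-induced genes fell: Ifit1, an antiviral protein, went from 447 ± 118 intensity units in CON to 12.1 ± 4.13 in LTCR (SD, n = 4), and Usp18 from 417 ± 203 to 13.5 ± 4.77. In both genes 4 of 4 LTCR arrays lay below 27, the value added before taking logs, so only a bound is given: CON was at least 16.1-fold higher for Ifit1 and at least 14.2-fold for Usp18 with LTCR set at 27. Isg15, a ubiquitin-like modifier, had a log2 change of -2.81 ± 0.20 (SE) and Ifi47 of -2.57 ± 0.28. Enzymes of glucose output rose: G6pc, glucose-6-phosphatase, went from 3078 ± 560 to 8234 ± 1508, a change of 1.41 ± 0.26, and Pck1, phosphoenolpyruvate carboxykinase, rose by 0.71 ± 0.14. Hspa5, the main chaperone of the endoplasmic reticulum, went from 5643 ± 312 to 2965 ± 750, a change of -0.95 ± 0.15. Limma called 1419 of 7357 probe sets, 554 higher and 865 lower, and 2351 had an unadjusted p under 0.05. In 1557, or 21.2%, the 8 arrays did not overlap between the groups, against 2.86% by chance here and in the other comparisons.

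Of 22 measured interferon and antigen processing genes, 16 fell and 0 rose in LTCR, and 18 fell when adjusted over the list alone (camera adjusted p = 2.32e-14; adjusted p = 0.138 with an estimated correlation). Of 24 genes for chaperones and stress of the endoplasmic reticulum, 12 fell and 0 rose, and adjusted over the list alone 12 fell and 1 rose. Manf fell by 1.22 ± 0.20 and Pdia3, a disulfide isomerase, by 1.10 ± 0.20 (adjusted p = 0.272 with an estimated correlation). Of 9 gluconeogenesis genes, 4 rose and 0 fell, and 5 rose adjusted over the list alone. The preset test gave adjusted p = 0.000179, and the list had adjusted p = 0.0587 with an estimated correlation. Of 22 genes of amino acid catabolism and the urea cycle, 7 rose (7 rose and 1 fell adjusted over the list alone). Tat, tyrosine aminotransferase, rose by 1.04 ± 0.15 and Tdo2, tryptophan dioxygenase, by 0.55 ± 0.09. That list had adjusted p = 0.199 with an estimated correlation. Of 29 cytosolic and mitochondrial chaperones, 8 rose and 1 fell (the same counts adjusted over the list alone). Hspa1b, an inducible heat shock protein, rose by 1.79 ± 0.39 and Hsph1 by 1.32 ± 0.26 (adjusted p = 0.272 with an estimated correlation). Of 27 ribosomal protein genes, 12 rose and 0 fell (15 rose and 1 fell adjusted over the list alone), including Rps18 by 0.59 ± 0.08 and Rpl10a by 0.59 ± 0.10, whose other probe set had the opposite sign without a call (adjusted p = 0.138 with an estimated correlation).

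Of 63 genes of oxidative phosphorylation, 14 rose and 1 fell in LTCR (16 and 1 adjusted over the list alone), with Ndufv1, a complex I subunit, at 0.61 ± 0.10 (adjusted p = 0.393 with an estimated correlation). Of 17 genes of the tricarboxylic acid cycle, 4 rose and 0 fell (4 adjusted over the list alone), with Suclg1 at 0.54 ± 0.09 (adjusted p = 0.409 with an estimated correlation). Of 16 lipoprotein genes, 7 rose and 3 fell (8 and 3 adjusted over the list alone). Apom rose by 0.98 ± 0.18 and Lcat, which esterifies plasma cholesterol, by 0.74 ± 0.14. The lipoprotein list had adjusted p = 0.293 with an estimated correlation. Of 18 glucocorticoid-responsive genes, 6 rose and 3 fell (7 and 3 adjusted over the list alone). Fkbp5 rose by 1.18 ± 0.16 and Mt2, a metallothionein, fell by 2.50 ± 0.50 (adjusted p = 0.189 with an estimated correlation). Of 6 cholangiocyte markers, 3 fell (3 adjusted over the list alone), among them the keratins Krt8, by 1.17 ± 0.16, and Krt18, by 1.02 ± 0.17, which hepatocytes also express (adjusted p = 0.2 with an estimated correlation). Kupffer cell and macrophage markers averaged -0.39 ± 0.22 (SD) in LTCR beside the falls of the interferon list (exact p = 0.0286, adjusted p = 0.2). Other scalings or filters, or the replicate block, ended the calls of the lists of amino acid catabolism, lipoproteins, the tricarboxylic acid cycle, glucocorticoid-responsive genes and cholangiocyte markers. Their adjusted p then lay between 0.0505 and 0.779.

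Other genes with large rises in LTCR were Zbtb16, a zinc finger transcription factor, by 2.17 ± 0.41, Hip1r by 1.83 ± 0.44, St3gal5, a ganglioside synthase, by 1.53 ± 0.18, Acot1 by 1.49 ± 0.49, Slc25a25 by 1.33 ± 0.23 and Lpin1 by 1.20 ± 0.20. Gadd45a, a growth arrest gene, fell, with a change of -3.32 ± 0.24 (2 of 4 LTCR arrays below 27), as did Wfdc2 (-2.34 ± 0.22), the transcriptional repressor Bcl6 (-2.11 ± 0.56) and Cyp4a12b (-1.96 ± 0.30). Dbp, a circadian transcription factor, fell by 1.17 ± 0.12 and Cd36 by 0.60 ± 0.17, while Igf1 rose by 0.49 ± 0.12 and Igfbp1, which binds it, by 1.14 ± 0.35. The lipogenic regulator Srebf1 fell by 0.90 ± 0.13 and the desaturase Fads1 rose by 0.51 ± 0.17. Fasn, fatty acid synthase, had -0.04 ± 0.22 (adjusted p = 0.936), Acly -0.31 ± 0.13 (adjusted p = 0.0881), Apoa4 0.11 ± 0.18 (adjusted p = 0.728) and Cpt1a -0.08 ± 0.11 (adjusted p = 0.664). With 1 array left out their signs turned for Fasn (0.085 without CON 3), Apoa4 (-0.016 without LTCR 1, and -0.032 with quantile normalization) and Cpt1a (0.0075 without LTCR 3). For the 39 genes past the threshold, the 4 LTCR arrays did not overlap the 4 CON arrays, and 35 stayed past it with each array left out. The calls of Acot1 (adjusted p = 0.0866 without LTCR 1), Igfbp1 (0.116 without CON 2, with a change of 0.76 ± 0.33), Fads1 (0.0851 without LTCR 4) and Cd36 (0.0727 without CON 1) ended.

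**Figure D2:**
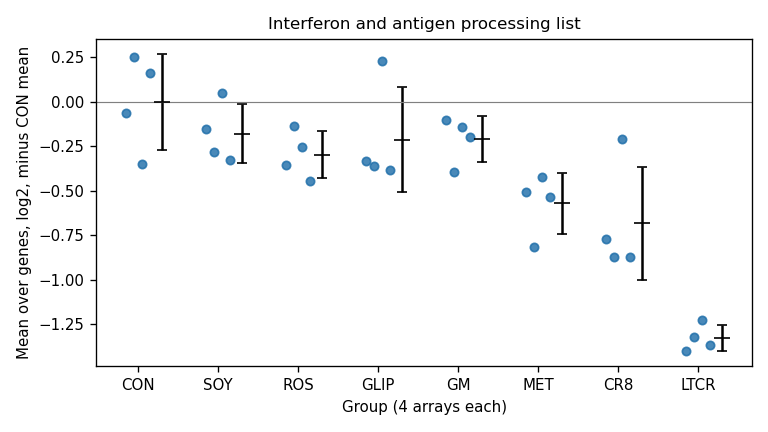
Points are arrays, and lines are the mean ± SD of the 4 arrays of each group (horizontal axis). The vertical axis is the mean of the 22 interferon and antigen processing genes on the log2 scale relative to the CON mean. LTCR arrays lay between -1.40 and -1.23, below all other arrays.

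Several interferon-induced genes fell after restriction for 8 weeks (CR8). Ifit1 went from 447 ± 118 in CON to 103 ± 47.9 (SD, n = 4). The log2 change was -1.91 ± 0.34 (SE), and Rsad2 fell by 1.45 ± 0.26, Ifit3 by 1.43 ± 0.23, Isg15 by 1.17 ± 0.20, Irf7 by 1.01 ± 0.20 and Irgm1 by 0.99 ± 0.17. Gadd45a fell by 1.34 ± 0.24 and Cyp4a12b by 1.41 ± 0.30. Hhex, a hepatic homeobox factor, rose by 1.26 ± 0.19, Tbx3 by 0.78 ± 0.17, Cyp2c39 by 0.58 ± 0.11 and Ncl, nucleolin, by 0.36 ± 0.09. Actg1, a cytoplasmic actin, fell by 1.06 ± 0.21, Apoa4 by 0.86 ± 0.18, Hspa5 by 0.71 ± 0.15, Manf by 0.90 ± 0.20 and Sqstm1 by 0.34 ± 0.08. Limma called 40 probe sets, 13 higher and 27 lower, or 18 and 18 with equal medians. There were 851 with an unadjusted p under 0.05 and 530, or 7.2%, that did not overlap.

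Of the 22 interferon and antigen processing genes, 7 fell in CR8 and 13 fell when adjusted over the list alone (adjusted p = 0.187 with an estimated correlation). Of the 24 endoplasmic reticulum genes, 2 fell and 8 fell adjusted over the list alone (adjusted p = 0.215 with an estimated correlation). Ribosomal protein genes had a median of 0.19, with 0 of 27 past the threshold in limma and 8 higher adjusted over the list alone, among them Rplp0 at 0.25 ± 0.07 (adjusted p = 0.0712). The list had adjusted p = 0.187 with an estimated correlation. Of 26 autophagy and lysosome genes, 1 fell and 5 fell adjusted over the list alone (adjusted p = 0.478 with an estimated correlation). Camera also called 3 lists with 0 genes past the threshold in limma. Gluconeogenesis had 1 of 9 genes higher adjusted over the list alone and G6pc at 0.32 ± 0.26 (adjusted p = 0.359 with an estimated correlation). Amino acid catabolism had 1 of 22 higher adjusted over the list alone and Tat at 0.51 ± 0.15 (adjusted p = 0.547 with an estimated correlation). Cholesterol synthesis had 0 of 16 adjusted over the list alone, Fdft1 at 0.35 ± 0.13 and Fdps at 0.83 ± 0.46 (adjusted p = 0.723 with an estimated correlation), and its mean difference of 0.251 was 0.104 without CR8 3. Other scalings or filters, or the replicate block, ended the calls of these 3 lists and of autophagy and lysosome genes (adjusted p between 0.0507 and 0.234). Kupffer cell and macrophage markers had a mean of -0.41 ± 0.27 (SD; exact p = 0.0571, adjusted p = 0.2) beside the interferon genes, with 0 of 16 past the threshold, 0 adjusted over the list alone and Mpeg1 at -0.78 ± 0.29 (adjusted p = 0.723 with an estimated correlation).

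Pck1 had -0.05 ± 0.14, Dbp -0.02 ± 0.12, Igfbp1 -0.12 ± 0.35, Igf1 0.26 ± 0.12 and Sult2a2 1.41 ± 0.93 in CR8, none past the threshold (adjusted p between 0.395 and 0.973). Pck1 and Dbp were at 0.0050 and 0.035 with median scaling. Dbp was at 0.0091 without CR8 3 and 0.0051 without CR8 4, and Igfbp1 at 0.14 without CON 3, 0.024 without CR8 1 and 0.12 without CR8 4. The 17 named genes past the threshold had arrays that did not overlap, and 7 of them stayed past it with each array left out. CON 3, CR8 1 and CR8 2 carried muscle transcripts. Without the 5 arrays that did, limma called 29 probe sets, 13 of them among the 40, and of the 17 genes only Ifit3 (-1.42 ± 0.28), Isg15 (-1.20 ± 0.25) and Irgm1 (-1.12 ± 0.20) stayed past the threshold, while 14 kept their direction at adjusted p between 0.0519 (Rsad2) and 0.201 (Tbx3). That fit held fewer arrays, 3 of CON and 2 of CR8. Limma called 25 probe sets without CON 1, 14 without CON 2, 63 without CON 3, 26 without CON 4, 26 without CR8 2, 68 without CR8 3 and 11 without CR8 4, and in a fit to CR8 and CON alone 16. Ended calls were those of Tbx3 (adjusted p = 0.0800 without CR8 2), Ncl (0.229), Cyp4a12b (0.0958), Sqstm1 (0.177), Apoa4 (0.0907) and Cyp2c39 (0.0517) without CR8 4, and Hspa5 (0.0643), Manf (0.0919), Irf7 (0.0644) and Actg1 (0.0643) without CON 2.

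LTCR against CR8 cannot separate duration from age at onset or the 77 kcal step. Slc25a25, a mitochondrial carrier, was higher in LTCR, going from 2255 ± 642 intensity units in CR8 to 5912 ± 492 (SD, n = 4). This was a log2 difference of 1.43 ± 0.23 (SE), and G6pc differed by 1.09 ± 0.26, Pck1 by 0.76 ± 0.14, Igfbp1 by 1.26 ± 0.35 and Apoa4 by 0.96 ± 0.18. Hspa1b was higher by 1.57 ± 0.39, Errfi1 by 1.20 ± 0.34, St3gal5 by 1.14 ± 0.18 and Hnf4a, a master regulator of hepatocyte genes, by 1.11 ± 0.18. Lower in LTCR were the cholesterol synthesis genes Msmo1, by a change of -1.80 ± 0.46, and Idi1, by -1.78 ± 0.51, with Sult2a2, a sulfotransferase, at -3.59 ± 0.93, Mt2 at -2.53 ± 0.50, Cyp26a1, which clears retinoic acid, at -2.34 ± 0.33 and Hao2 at -1.71 ± 0.38. Dbp differed by -1.15 ± 0.12 and Gadd45a by -1.98 ± 0.24. Limma called 882 probe sets, 342 higher and 540 lower in LTCR, with 1947 at unadjusted p under 0.05 and 1188, or 16.2%, not overlapping.

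Of the 22 interferon and antigen processing genes, 10 were lower in LTCR than in CR8 and 11 adjusted over the list alone, with Ifi47 at -1.90 ± 0.28 and Isg15 at -1.65 ± 0.20 (adjusted p = 0.419 with an estimated correlation). Gluconeogenesis had 3 of 9 genes higher and 5 adjusted over the list alone (adjusted p = 0.388 with an estimated correlation). Amino acid catabolism had 3 of 22 higher and 3 adjusted over the list alone, with Tat at 0.53 ± 0.15 and Tdo2 at 0.47 ± 0.09, whose other probe set had the opposite sign without a call (adjusted p = 0.431 with an estimated correlation). Oxidative phosphorylation had 10 of 63 higher and 10 adjusted over the list alone, with Ndufs3 at 0.31 ± 0.07 (adjusted p = 0.431 with an estimated correlation), and the mean difference of 0.102 was 0.0639 without CR8 3. The tricarboxylic acid cycle had 2 of 17 higher and 2 adjusted over the list alone, with Suclg1 at 0.42 ± 0.09 (adjusted p = 0.449 with an estimated correlation). Among glucocorticoid-responsive genes 7 of 18 were higher and 2 lower (10 and 4 adjusted over the list alone), with Fkbp5 at 0.63 ± 0.16 and Lpin1 at 0.76 ± 0.20 (adjusted p = 0.419 with an estimated correlation). Cytosolic and mitochondrial chaperones had 7 of 29 higher and 1 lower (8 and 1 adjusted over the list alone; adjusted p = 0.419 with an estimated correlation), lipoproteins 5 of 16 higher and 1 lower (6 and 2 adjusted over the list alone; adjusted p = 0.419 with an estimated correlation), and ribosomal proteins 3 of 27 higher (3 adjusted over the list alone; adjusted p = 0.481 with an estimated correlation). Other scalings or filters ended the calls of the lists of amino acid catabolism, lipoproteins, the tricarboxylic acid cycle, ribosomal proteins and glucocorticoid-responsive genes (adjusted p between 0.0558 and 0.393). CR8 1 and CR8 2 carried muscle transcripts, and without the 5 arrays that did, limma called 423 probe sets. Without CR8 2 alone it called 572, and in a fit to both groups alone 488. Of 25 named genes, 19 stayed past the threshold with each array left out. Calls ended for Igfbp1 (adjusted p = 0.0773 without CR8 4), Errfi1 (0.105 without CR8 2), Tat (0.0923) and Lpin1 (0.0799, with a difference of 0.49 ± 0.17) without LTCR 4, and Sult2a2 (0.0522) and Idi1 (0.107) without CR8 3.

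Several genes of fatty acid and cholesterol synthesis rose with metformin. Fads1, a fatty acid desaturase, went from 3614 ± 179 intensity units in CON to 7372 ± 2213 in MET (SD, n = 4). The log2 change was 0.97 ± 0.17 (SE), and Srebf1 rose by 0.60 ± 0.13, Fasn by 0.76 ± 0.22, the citrate carrier Slc25a1 by 0.57 ± 0.10, Mid1ip1 by 0.83 ± 0.21 and Elovl5 by 0.46 ± 0.13. Of the sterol enzymes, Fdps rose by 2.17 ± 0.46, Nsdhl by 0.99 ± 0.22, Lss by 0.87 ± 0.18 and Fdft1 by 0.45 ± 0.13. Several interferon-induced genes fell, with Ifit1 from 447 ± 118 to 127 ± 76.0, a change of -1.79 ± 0.34. Limma called 307 probe sets, 135 higher and 172 lower, or 191 and 65 with equal medians. There were 1330 with an unadjusted p under 0.05 and 739, or 10%, that did not overlap.

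Of 15 lipogenesis genes, 5 rose in MET and 10 rose adjusted over the list alone (adjusted p = 0.0731 with an estimated correlation), and the mean difference of 0.460 was 0.302 without MET 1. Acly had 0.38 ± 0.13 (adjusted p = 0.0854) and Thrsp 1.10 ± 0.37 (adjusted p = 0.0866). Of 16 cholesterol synthesis genes, 5 rose and 10 rose adjusted over the list alone (adjusted p = 0.121 with an estimated correlation). Of 11 glycolysis genes, 1 rose, Pklr, the liver pyruvate kinase, by 0.66 ± 0.13, and 4 rose adjusted over the list alone (adjusted p = 0.0414 with an estimated correlation). Gluconeogenesis had 1 of 9 genes higher, Fbp1 by 0.21 ± 0.06, and 3 adjusted over the list alone (adjusted p = 0.169 with an estimated correlation). G6pc had 0.59 ± 0.26 and Pck1 -0.28 ± 0.14, both short of the threshold (adjusted p = 0.213 and 0.302). Of the 22 interferon and antigen processing genes, 9 fell and 14 fell adjusted over the list alone (adjusted p = 0.246 with an estimated correlation). Irgm1 had a change of -1.17 ± 0.17, Gbp3 of -1.10 ± 0.25, Usp18 of -1.28 ± 0.35 and Isg15 of -0.70 ± 0.20. Outside the list, the aminopeptidase Lap3 fell by 1.15 ± 0.19. Kupffer cell and macrophage markers averaged 0.28 ± 0.17 (SD; exact p = 0.0857, adjusted p = 0.2) and endothelial markers 0.30 ± 0.01 (SD; exact p = 0.0286, adjusted p = 0.2) in the same arrays. In these lists 0 of 16 and 0 of 13 passed the threshold, and 0 of each adjusted over the list alone (adjusted p = 0.665 and 0.236 with an estimated correlation).

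Endoplasmic reticulum genes had a median of -0.26 in MET, with 1 of 24, Pdia3, falling by 0.85 ± 0.20, 3 lower adjusted over the list alone, and Hspa5 at -0.49 ± 0.15 (adjusted p = 0.0566; list adjusted p = 0.516 with an estimated correlation). Ribosomal proteins had 5 of 27 higher and 8 adjusted over the list alone, including Rpl19 by 0.39 ± 0.08 and Rpl41 by 0.48 ± 0.10 (adjusted p = 0.169 with an estimated correlation). Of 16 lipoprotein genes, 3 rose, Apoe by 0.38 ± 0.10, and 1 fell, the cholesterol exporter Abca1 by 0.60 ± 0.11 (8 and 2 adjusted over the list alone; adjusted p = 0.169 with an estimated correlation). Oxidative phosphorylation had 3 of 63 higher and 1 lower (13 and 5 adjusted over the list alone; adjusted p = 0.406 with an estimated correlation), and the mean difference of 0.0508 was 0.0256 without MET 2. Of 8 female-predominant genes, 2 rose, Cyp2b13 by 2.04 ± 0.60 and Cyp17a1 by 1.00 ± 0.28 (3 higher and 1 lower adjusted over the list alone; adjusted p = 0.474 with an estimated correlation), and without CON 2 the mean difference of 0.462 was 0.256. Of 6 cholangiocyte markers, 1 fell, Krt18 by 0.93 ± 0.17, and 2 fell adjusted over the list alone (adjusted p = 0.265 with an estimated correlation). The lists of circadian output and of growth hormone, IGF and insulin signalling were called higher with 0 of 16 and 0 of 19 genes past the threshold and 0 adjusted over the list alone (adjusted p = 0.169 for each with an estimated correlation). Other scalings or filters ended the calls of these 2 lists and of gluconeogenesis, lipoproteins, female-predominant genes, macrophage markers and cholangiocyte markers (adjusted p between 0.0511 and 0.763). Other rises were those of Avpi1, by 1.26 ± 0.27, Brca2, by 1.15 ± 0.29, and Qdpr, by 0.63 ± 0.10, and Cyp4a12b fell by 1.5 ± 0.30. Cpt1a had 0.25 ± 0.11, Pdk4 -0.33 ± 0.41 and Igfbp1 -0.25 ± 0.35, none past the threshold (adjusted p = 0.212, 0.738 and 0.763), and without CON 3 Pdk4 was at 0.094 and Igfbp1 at 0.0040.

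In MET the arrays of Elovl5, Fdps, Cyp17a1, Cyp2b13 and Fasn overlapped those of CON, and those of the other 25 named genes past the threshold did not. Limma called 156 probe sets without CON 1, 173 without CON 3, 140 without CON 4, 195 without MET 3, 199 without MET 4, 95 without the 5 arrays with muscle transcripts and 33 in a fit to MET and CON alone, where 9 of the 30 named genes passed. With each array left out 17 of the 30 stayed past the threshold. Calls ended for Usp18 (adjusted p = 0.121), Brca2 (0.0827) and Cyp2b13 (0.179) without CON 2, Fdft1 (0.0992), Apoe (0.0723), Pdia3 (0.0589) and Isg15 (0.115) without CON 1, Cyp17a1 (0.139), Fbp1 (0.106) and Gbp3 (0.0509) without CON 4, Elovl5 (0.110) without CON 3, and Fasn (0.175, with a change of 0.45 ± 0.18) and Mid1ip1 (0.0765) without MET 1. With SOY in place of CON limma called 317, of which 135 were among the 307.

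**Figure D3:**
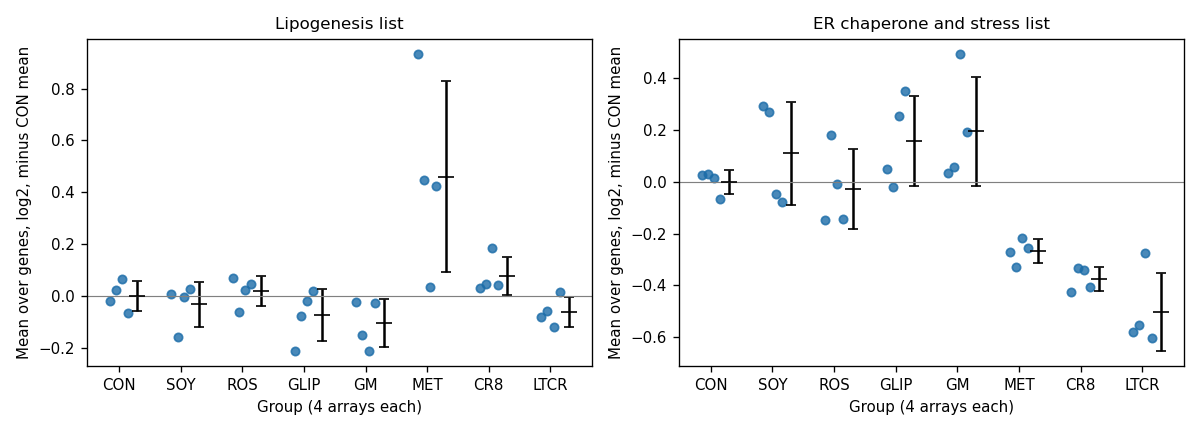
Points are arrays and lines the mean ± SD of the 4 arrays of each group (horizontal axes). Vertical axes give the mean over the 15 lipogenesis genes (left) and the 24 endoplasmic reticulum (ER) chaperone and stress genes (right) on the log2 scale relative to the CON mean. MET arrays spread from 0.03 to 0.93 on the lipogenesis list, and LTCR arrays from -0.60 to -0.28 on the ER list.

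Glipizide changed few transcripts. Tbx3, a T-box transcription factor, went from 69.3 ± 13.5 intensity units in CON to 179 ± 19.6 in GLIP (SD, n = 4). This was a log2 change of 1.10 ± 0.17 (SE). Pdia4, a disulfide isomerase of the endoplasmic reticulum, rose by 1.10 ± 0.21, Cflar, an inhibitor of caspase 8, by 1.09 ± 0.23, Sdc4, a syndecan, by 0.78 ± 0.14, Ugcg, glucosylceramide synthase, by 0.66 ± 0.13 and Rnasek by 0.41 ± 0.09, and Tpmt, thiopurine methyltransferase, fell by 0.55 ± 0.10. Limma called 10 probe sets, 9 higher and 1 lower, with 689 at unadjusted p under 0.05 and 400, or 5.44%, not overlapping. Hspa5 had 0.39 ± 0.15, Ifit1 -1.31 ± 0.34, Pck1 -0.24 ± 0.14, Fasn 0.17 ± 0.22, Igfbp1 -0.28 ± 0.35 and G6pc -0.08 ± 0.26, none past the threshold (adjusted p between 0.162 and 0.963). G6pc was at 0.019 without CON 4 and 0.10 without GLIP 3.

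Camera called 11 lists in GLIP, and with an estimated correlation none was called (adjusted p = 0.497 to 0.708 with an estimated correlation). In the endoplasmic reticulum list 1 of 24 genes rose (4 higher and 1 lower adjusted over the list alone). In the others 0 genes passed: 27 genes of fatty acid oxidation with a median of -0.16, 17 of the tricarboxylic acid cycle with -0.11, 63 of oxidative phosphorylation with -0.07, 29 chaperones with 0.18, 27 ribosomal proteins with 0.11, 22 interferon genes with -0.08, 16 macrophage markers with 0.43, 13 endothelial markers with 0.24, 6 cholangiocyte markers with -0.28 and 10 muscle markers with -0.50. Adjusted over the list alone, 1 chaperone and 3 ribosomal protein genes were higher, 2 interferon genes and 2 cholangiocyte markers were lower, and 0 passed in the remaining 6. The array CON 3 held muscle transcripts beside the lower muscle markers of GLIP, and the difference of the muscle list means, -0.697, was -0.232 without CON 3. GLIP 3 stood at 1.38 on the macrophage list, whose difference of 0.355 was 0.014 without it, and those of fatty acid oxidation (-0.191) and cholangiocyte markers (-0.207) were -0.0908 and -0.101 without GLIP 4. The difference for endoplasmic reticulum genes, 0.158, was 0.0935 without GLIP 4, for interferon genes, -0.213, it was -0.129 without CON 2, for oxidative phosphorylation, -0.0819, it was -0.0523 without CON 3, and for endothelial markers, 0.284, it was 0.185 without GLIP 3. A stricter filter or none ended the calls of interferon genes, endothelial markers and cholangiocyte markers (adjusted p between 0.0599 and 0.332). Limma called 6 probe sets without CON 3, 2 without CON 4, 1 without GLIP 1, 4 without GLIP 2, 5 without GLIP 3, 2 without GLIP 4, 2 without the arrays with muscle transcripts, 6 without a filter, 6 with median scaling, 4 with the replicate block and 5 against SOY. Of the 7 named genes, Tbx3 alone stayed past the threshold with each array left out. The others reached adjusted p = 0.128 for Pdia4 without GLIP 4, 0.164 for Cflar without CON 4, 0.271 for Rnasek without GLIP 4, and 0.0588 for Sdc4, 0.119 for Ugcg and 0.0814 for Tpmt without GLIP 1.

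Glipizide with metformin (GM) raised Irs2 and Hip1r. Irs2, an insulin receptor substrate, went from 43.5 ± 20.2 intensity units in CON to 253 ± 132 in GM (SD, n = 4). The log2 change was 1.87 ± 0.40 (SE), and Hip1r rose by 2.15 ± 0.44. Bag3, a partner of heat shock proteins, rose by 0.84 ± 0.15, Pdia4 by 0.90 ± 0.21, Sec61b, of the protein translocation channel, by 0.83 ± 0.19 and the proteasome subunit Psmd4 by 0.44 ± 0.11. Mme, the peptidase neprilysin, fell by 1.36 ± 0.21, Gsta2, a glutathione transferase, by 1.23 ± 0.29, Lap3 by 0.73 ± 0.19 and Ifih1, a sensor of viral RNA, by 0.70 ± 0.18. Limma called 114 probe sets, 64 higher and 50 lower. With equal medians it called 427, 408 higher and 19 lower. An unadjusted p under 0.05 was found for 1304, and 772, or 10.5%, did not overlap.

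Of 19 genes of growth hormone, IGF and insulin signalling, 1 rose in GM (5 higher and 1 lower adjusted over the list alone; adjusted p = 0.0310 with an estimated correlation). The endoplasmic reticulum list had 2 of 24 higher (3 adjusted over the list alone), chaperones 1 of 29 (4), the proteasome 1 of 42 (1) and acute phase genes 0 of 25 (4 higher and 1 lower), each with adjusted p = 0.345 with an estimated correlation. The acute phase list stood at 1.29 in GM 3, and without that array its mean difference of 0.395 was 0.0975 and that of the endoplasmic reticulum list, 0.194, was 0.0951. Ribosomal proteins had 1 of 27 higher, Rpl19 by 0.32 ± 0.08, whose other probe set had the opposite sign without a call, and 5 adjusted over the list alone (adjusted p = 0.315 with an estimated correlation). Lipoproteins had 0 of 16 past the threshold and 6 higher adjusted over the list alone (adjusted p = 0.315 with an estimated correlation), and gluconeogenesis 0 of 9 and 2 higher adjusted over the list alone (adjusted p = 0.216 with an estimated correlation), with Pck1 at 0.06 ± 0.14 and G6pc at 0.17 ± 0.26. Quantile normalization ended the calls of ribosomal proteins, lipoproteins and gluconeogenesis (adjusted p between 0.0566 and 0.8), and Pck1 was then at -0.0059. Tbx3 rose by 0.77 ± 0.17, Mtf1 by 0.88 ± 0.21, the fatty acid transporter Slc27a4 by 0.76 ± 0.15 and F12, coagulation factor XII, by 0.65 ± 0.10. Fasn had 0.18 ± 0.22, Srebf1 -0.33 ± 0.13, Nsdhl 0.07 ± 0.22, Hspa5 0.20 ± 0.15, Cyp2b13 -0.94 ± 0.60, Cyp4a12b -0.49 ± 0.30 and Saa3 1.22 ± 0.35, none past the threshold (adjusted p between 0.0668 and 0.893). Single arrays turned the sign of Pck1 (-0.018 without CON 3), Nsdhl (-0.088 without CON 4 and -0.091 without GM 3) and G6pc (-0.11 without GM 1).

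Limma called 48 probe sets in GM without CON 1, 65 without CON 3, 28 without CON 4, 30 without GM 1, 28 without GM 4, 33 without the arrays with muscle transcripts, 57 without a filter, 4 in a fit to GM and CON alone and 5 against SOY, 2 of these among the 114. Of 15 named genes past the threshold, whose arrays did not overlap, Hip1r, Bag3, F12 and Mme stayed past it with each array left out. Calls ended at adjusted p = 0.0767 for Irs2, 0.0721 for Pdia4 and 0.106 for Psmd4 without GM 4, 0.0734 for Sec61b and 0.0866 for Gsta2 without GM 3, 0.173 for Lap3 and 0.136 for Rpl19 without GM 1, 0.107 for Ifih1 and 0.0957 for Mtf1 without CON 2, 0.0578 for Tbx3 without CON 3 and 0.0564 for Slc27a4 without CON 4.

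GM was compared with MET for what glipizide adds to metformin. Some lipogenic genes were lower in GM: Srebf1 had 2007 ± 122 intensity units against 3902 ± 757 in MET (SD, n = 4). The log2 difference was -0.93 ± 0.13 (SE) for Srebf1, -1.86 ± 0.37 for Thrsp, which promotes lipogenesis, and -0.80 ± 0.17 for Fads1. Some endoplasmic reticulum genes of protein folding were higher, with Creld2 at 1.15 ± 0.22, Manf at 0.89 ± 0.20, Dnajb11 at 0.88 ± 0.18, Dnajc3 at 0.76 ± 0.15 and Hspa5 at 0.69 ± 0.15. Saa3, an acute phase protein, was higher by 1.98 ± 0.35 and Lrg1 by 0.90 ± 0.25. Limma called 193 probe sets, 96 higher and 97 lower, or 176 and 58 with equal medians, with 1312 at unadjusted p under 0.05 and 630, or 8.56%, not overlapping. In a fit to GM and MET alone it called 0, with 1018 at unadjusted p under 0.05.

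Of 15 lipogenesis genes, 5 were lower in GM than in MET and 8 adjusted over the list alone (adjusted p = 0.108 with an estimated correlation). Cholesterol synthesis had 2 of 16 lower, Nsdhl at -0.91 ± 0.22 and Fdft1 at -0.48 ± 0.13, and 5 adjusted over the list alone (adjusted p = 0.212 with an estimated correlation). Of 24 endoplasmic reticulum genes, 7 were higher and 10 adjusted over the list alone (adjusted p = 0.117 with an estimated correlation). The proteasome had 7 of 42 higher, with Psmd4 at 0.54 ± 0.11 and Psma7 at 0.45 ± 0.10, and 14 adjusted over the list alone (adjusted p = 0.117 with an estimated correlation). Of 8 female-predominant genes, 3 were lower and 4 adjusted over the list alone (adjusted p = 0.117 with an estimated correlation), with Cyp2b13 at -2.98 ± 0.60 and Hao2 at -1.53 ± 0.38. Of 9 male-predominant genes, 0 passed and 3 were higher adjusted over the list alone (adjusted p = 0.276 with an estimated correlation). Acute phase genes had 2 of 25 higher (7 adjusted over the list alone; adjusted p = 0.212 with an estimated correlation), chaperones 0 of 29 (2 higher adjusted over the list alone; adjusted p = 0.212 with an estimated correlation) and interferon genes 2 of 22, Iigp1 at 0.69 ± 0.18 and Irgm1 at 0.64 ± 0.17 (6 adjusted over the list alone; adjusted p = 0.416 with an estimated correlation). Oxidative phosphorylation had 2 of 63 lower, Ndufb8 at -0.46 ± 0.11 (5 adjusted over the list alone; adjusted p = 0.281 with an estimated correlation), the tricarboxylic acid cycle 1 of 17 (2 adjusted over the list alone; adjusted p = 0.281 with an estimated correlation), circadian output 1 of 16 (3 adjusted over the list alone; adjusted p = 0.182 with an estimated correlation) and endothelial markers 0 of 13 (0 adjusted over the list alone; adjusted p = 0.438 with an estimated correlation). Also lower in GM were Mme at -1.65 ± 0.21, Ada, adenosine deaminase, at -1.42 ± 0.37, Pold2 at -1.30 ± 0.25, Star at -1.08 ± 0.29 and Cyp2b10 at -1.08 ± 0.24.

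Another scaling, added value or filter ended the call of endothelial markers (adjusted p between 0.0543 and 0.0978). Without GM 3 their mean difference of -0.241 was -0.0728, that of acute phase genes, 0.620, was 0.323 and that of oxidative phosphorylation, -0.123, was -0.0812. Arrays of Thrsp, Fads1 and Hao2 overlapped between GM and MET. Limma called 108 probe sets without GM 2, 94 without GM 3, 105 without GM 4, 99 without MET 2 and 79 without the 3 arrays with high acute phase transcripts, of which GM 3 was 1. Of 24 named genes 12 stayed past the threshold with each array left out. Calls ended for Lrg1 (adjusted p = 0.186), Hao2 (0.109), Ndufb8 (0.0881), Hspa5 (0.0554) and Cyp2b10 (0.0557) without GM 3, Fdft1 (0.132), Star (0.123), Ada (0.114) and Nsdhl (0.0749) without GM 2, and Iigp1 (0.142), Irgm1 (0.0958) and Manf (0.0676) without MET 2.

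Against glipizide alone, the combination changed no probe set past the threshold. Of the genes with the smallest p, Sec62, of the translocation channel, had -0.66 ± 0.15, Rdx -0.42 ± 0.10 and F12 0.42 ± 0.10 (SE; adjusted p = 0.320 for each). Of the 2 other probe sets of Sec62, 1 had the opposite sign. Pck1 had 0.30 ± 0.14 (adjusted p = 0.539) and Igfbp1 0.83 ± 0.35 (adjusted p = 0.496). Limma called 0 probe sets, 675 had an unadjusted p under 0.05, and 371, or 5.04%, did not overlap. Without GM 2 it called 2, and with median scaling 1. Camera called 10 lists, none with an estimated correlation: gluconeogenesis (median 0.23; adjusted p = 0.0862 with an estimated correlation), fatty acid oxidation (0.25; 0.377), bile acid metabolism (0.10; 0.137), lipoproteins (0.06; 0.329), oxidative phosphorylation (0.07; 0.691), conjugation enzymes (-0.09; 0.329), the proteasome (0.09; 0.286), growth hormone and insulin signalling (0.11; 0.0862), acute phase (0.16; 0.632) and macrophage markers (-0.40; 0.632). Without GM 3 the mean difference of the acute phase list, 0.235, turned to -0.0625, without GLIP 3 that of macrophage markers, -0.335, to 0.0061, and without GM 4 that of oxidative phosphorylation, 0.0099, to -0.014. Single arrays also took that of fatty acid oxidation from 0.201 to 0.101 (GLIP 4), of lipoproteins from 0.0506 to 0.0245 (GM 1), of bile acid metabolism from 0.0945 to 0.0621 (GLIP 3), of gluconeogenesis from 0.189 to 0.124 (GLIP 3) and of the proteasome from 0.0794 to 0.0528 (GLIP 1). In these 10 lists 0 genes passed, and adjusted over the list alone 1 gene of fatty acid oxidation and 1 of oxidative phosphorylation were higher. Other scalings or filters ended the calls of bile acid metabolism, lipoproteins, oxidative phosphorylation, conjugation enzymes, insulin signalling and acute phase genes (adjusted p between 0.0623 and 0.961). Under quantile normalization the median of the oxidative phosphorylation list was 0.02, with the opposite direction in camera.

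Rosiglitazone lowered Apoa4, an apolipoprotein, from 12400 ± 679 intensity units in CON to 3879 ± 960 (SD, n = 4). The log2 change was -1.70 ± 0.18 (SE). Rundc3a fell by 1.40 ± 0.16, Cyp4a12b by 1.5 ± 0.30, Wfdc2 by 1.14 ± 0.22, Upp2, uridine phosphorylase, by 1.02 ± 0.19, Krt8 by 0.77 ± 0.16 and Sqstm1, an autophagy receptor, by 0.40 ± 0.08, and Ugcg rose by 0.81 ± 0.13. Cd36 and Fabp4, targets of PPAR gamma in fat, had -0.02 ± 0.17 and 0.53 ± 0.30 (adjusted p = 0.990 and 0.686), and Pdk4 had 0.54 ± 0.41 (adjusted p = 0.834). Cd36 was at 0.10 without CON 1, 0.073 without CON 3, 0.061 without ROS 1 and 0.042 without ROS 2, and Pdk4 at -0.041 without ROS 4. Limma called 10 probe sets, 2 higher and 8 lower, with 619 at unadjusted p under 0.05 and 357, or 4.85%, not overlapping. Camera called 4 lists: autophagy and lysosome with 1 of 26 lower (5 adjusted over the list alone; adjusted p = 0.223 with an estimated correlation), interferon genes with 0 of 22 (4 lower adjusted over the list alone; adjusted p = 0.555 with an estimated correlation; Ifit3 -0.87 ± 0.23), gluconeogenesis with 0 of 9 (1 higher adjusted over the list alone; adjusted p = 0.223 with an estimated correlation; Pcx 0.31 ± 0.10) and ribosomal proteins with 0 of 27 (0 adjusted over the list alone; adjusted p = 0.223 with an estimated correlation; Rpl19 0.25 ± 0.08, its other probe set of opposite sign). The gluconeogenesis call ended with median scaling and without a filter (adjusted p between 0.0548 and 0.0734). ROS 4 held muscle transcripts and ROS 2 acute phase transcripts. Limma called 4 without CON 4, 5 in a fit to ROS and CON alone and 34 against SOY, 9 of these among the 10. Apoa4, Rundc3a and Ugcg stayed past the threshold with each array left out, and calls ended for Krt8 (adjusted p = 0.151), Wfdc2 (0.103) and Upp2 (0.0832) without CON 4 and for Cyp4a12b (0.151) and Sqstm1 (0.123) without ROS 2.

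Soy isoflavones changed no probe set past the threshold. Pax2 had a log2 difference from CON of -1.10 ± 0.25 (SE), Csf3 -1.17 ± 0.27 and B4galnt1, a ganglioside synthase, 0.47 ± 0.12 (adjusted p = 0.391 for each, n = 4), and Ifit1 had -0.19 ± 0.34 (adjusted p = 0.929) and Cyp4a12b 0.07 ± 0.30 (adjusted p = 0.971), or -0.021 with quantile normalization. Limma called 0 probe sets, with 601 at unadjusted p under 0.05 and 394, or 5.36%, not overlapping. Without SOY 3 it called 1. Camera called 7 lists with 0 genes past the threshold: amino acid catabolism (median 0.08), lipoproteins (0.08), xenobiotic cytochromes P450 (0.12), endoplasmic reticulum genes (0.12), the proteasome (0.05), ribosomal proteins (0.06) and acute phase genes (0.20), with adjusted p = 0.545 to 0.596 with an estimated correlation. Without SOY 2 the mean difference of the acute phase list, 0.182, turned to -0.0366, and without CON 2 that of the cytochromes P450, 0.117, was 0.025. That of endoplasmic reticulum genes, 0.110, was 0.0488 without SOY 1, that of the proteasome, 0.0448, was 0.0204 without SOY 2 and that of ribosomal proteins, 0.0388, was 0.0186 without SOY 4. Adjusted over the list alone, 1 cytochrome P450 gene and 1 ribosomal protein gene were higher. With quantile normalization camera called 0 of the 7, their adjusted p lying between 0.327 and 0.845. The lipoprotein median was then 0.00, with the opposite direction in camera.

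The treatments were set beside LTCR to ask which resembled it. Of the 40 probe sets called in CR8, 31 were called in the same direction in LTCR, among them those of Ifit1, Isg15, Gadd45a, Hspa5 and Cyp4a12b. Of the 307 of MET, 190 were, of 114 of GM 48, of 10 of ROS 7 and of 10 of GLIP 3. Opposite calls numbered 0 for CR8, 2 for MET, 3 for GM, 0 for ROS and 1 for GLIP. Independent lists of these sizes would share 4.15, 30.4, 10.7, 1.09 and 0.795, and an unchanged group simulated against the same controls shared 0.01 on average, at most 1. With split CON arrays, the covariance with LTCR was 0.0295 ± 0.00479 (jackknife SE) for CR8, 0.0342 ± 0.0113 for MET, 0.0115 ± 0.00157 for ROS, 0.00716 ± 0.00576 for GM, 0.00569 ± 0.0108 for GLIP and -0.00891 ± 0.00557 for SOY.

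With the CON arrays shared, the covariances were 0.0507 for CR8, 0.0553 for MET, 0.0326 for ROS, 0.0283 for GM, 0.0268 for GLIP and 0.0122 for SOY, against 0.0223 in simulated unchanged groups. Correlations across probe sets, which are not independent replicates, were 0.507, 0.496, 0.361, 0.259, 0.285 and 0.140 with shared controls (0.5 simulated, no chance level as LTCR was unchanged too) and 0.247, 0.257, 0.103, 0.0559, 0.0499 and -0.0765 with split controls. The LTCR score averaged 1.19 ± 0.13 in LTCR (SD, n = 4), 0.46 ± 0.16 in MET, 0.40 ± 0.06 in CR8, 0.27 ± 0.11 in GM, 0.24 ± 0.01 in ROS, 0.21 ± 0.15 in GLIP and 0.11 ± 0.07 in SOY, and as it was built from the CON arrays every other group tends to lie above 0. Of 15 exact permutation tests between treatments, 5 reached the smallest p possible, 0.0286 (adjusted p = 0.0857), and none passed after adjustment. These were CR8 and MET against ROS and SOY, and ROS against SOY, each with 4 of 4 arrays higher. The score of CR8 minus that of MET was -0.07 (exact p = 0.543, adjusted p = 0.582), which does not show that they act alike.

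**Figure D4:**
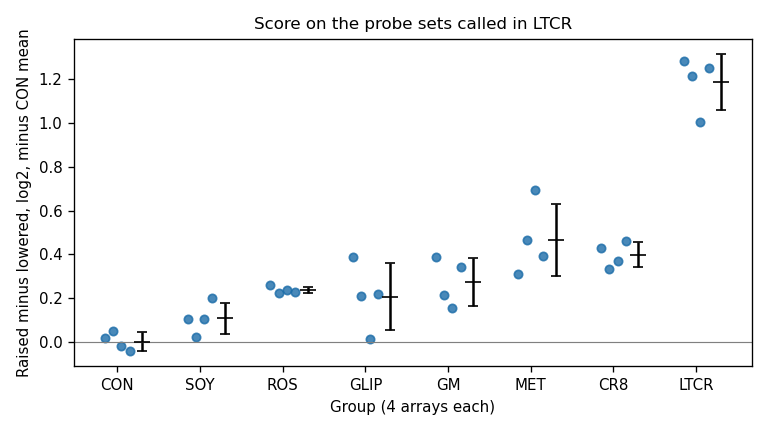
Points are arrays and lines the mean ± SD of the 4 arrays of each group (horizontal axis). The vertical axis is the LTCR score, the mean of probe sets called higher in LTCR minus that of those called lower, on the log2 scale relative to CON. LTCR arrays lay between 1.00 and 1.29, and the highest array of another group, in MET, at 0.69.

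Markers of other cell types and RNA quality were compared with CON. Cholangiocyte markers averaged -0.48 ± 0.11 in LTCR, -0.30 ± 0.15 in MET, -0.24 ± 0.15 in GM and -0.20 ± 0.08 in ROS (SD, n = 4), each with exact p = 0.0286 and adjusted p = 0.05. CR8, GLIP and SOY had -0.19 to -0.21, so CON may stand high. Neutrophil and myeloid markers averaged -0.56 ± 0.19 in LTCR (exact p = 0.0286, adjusted p = 0.2). The 3' to 5' signal ratio of Gapdh, a sign of RNA integrity, was 0.844 ± 0.0978 in CON and between 0.802 and 0.912 in the other groups (exact p of at least 0.229, adjusted p of at least 0.880), and that of actin 1.75 ± 0.229 in CON and between 1.57 and 2.04 elsewhere (exact p of at least 0.2, adjusted p of at least 0.6). The control probe set for 18S ribosomal RNA averaged 589 ± 60.5 intensity units in CON, 362 ± 185 in LTCR (exact p = 0.0857, adjusted p = 0.3) and 405 ± 158 in CR8 (exact p = 0.0571, adjusted p = 0.3), with 3 of 4 arrays below all CON arrays in each, and 827 ± 256 in ROS (exact p = 0.143, adjusted p = 0.320), with 3 of 4 above and ROS 1, at 467, below all CON arrays. None passed after adjustment. Muscle transcripts were high in CON 3, CR8 1, CR8 2, ROS 4 and SOY 3, where the muscle list stood between 0.75 and 1.73 against at most 0.18 in the other 27 arrays.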

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

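The counts of calls over other splits and the test for muscle tissue were chosen before their results were seen, and the tests on interferon genes, on the scaling of the muscle arrays and on lipogenesis in MET only after. The 8 arrays of a comparison can be split into 4 and 4 in 35 ways. Only 1 split, the real one, gave as many calls (real count, highest other) in LTCR (1419, 104), CR8 (40, 18), MET (307, 8), GLIP (10, 3), GM (114, 1) and ROS (10, 0) against CON, in LTCR against CR8 (882, 198) and GM against MET (193, 14). This argues against chance there but cannot exclude it, 1 of 35 being the lowest share possible, unadjusted over 10 comparisons. For SOY against CON (0 calls in limma, 601 probe sets at unadjusted p under 0.05, highest other 0) and GM against GLIP (0 calls in limma, 675 at unadjusted p under 0.05, highest other 12), the real count of 0 is reached by any split (35 of 35), so the splits test nothing there. The split of GM and GLIP with 12 calls set GM 3 with GLIP 1, GLIP 3 and GLIP 4, more than the real one, while the median of the other splits was 0. This may point to a structure of these arrays, which was not tested.

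Interferon and antigen processing genes averaged -1.33 ± 0.07 in LTCR, -0.68 ± 0.32 in CR8 and -0.57 ± 0.17 in MET relative to CON (SD, n = 4), whose own SD was 0.27. All 7 groups averaged below CON (SOY -0.18), so CON may stand high. High CON arrays alone were argued against in LTCR, and in MET only relative to SOY, the group nearest CON. In both, 4 of 4 arrays lay below all SOY arrays (exact p = 0.0286, adjusted p = 0.0429 over 6 tests, differences -1.15 and -0.39). MET 3 (-0.42) lay above ROS 4 (-0.45). A loss of macrophages was argued against in LTCR and MET, where the interferon list minus the macrophage list differed from CON by -0.94 and -0.85, with 4 of 4 arrays below all CON arrays (exact p = 0.0286, adjusted p = 0.0429). In MET a rise of the macrophage list, by 0.28, is part of the -0.85. In LTCR other immune markers were also low, neutrophil and myeloid markers at -0.56 ± 0.19 (p above), class II genes of antigen-presenting cells at -0.52 ± 0.34 (exact p = 0.0857, adjusted p = 0.6) and B and plasma cell markers at -0.35 ± 0.25 (exact p = 0.114, adjusted p = 0.4), so a wider change in immune cells was left open there. In CR8 neither was excluded, since 3 of 4 arrays lay below SOY (exact p = 0.0857, adjusted p = 0.103) and the difference between the lists was -0.27 (exact p = 0.257). A lower interferon response in LTCR and MET may be biological, a hypothesis found and tested on the same arrays. Infection and hybridization day were not tested.

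Muscle transcripts were high in the 5 arrays named above. On 21 other muscle genes, 5 of these 5 arrays stood above the other 27, the lowest at 0.48 against at most 0.26, and Acta1, skeletal muscle actin, was between 2874 and 10461 against at most 440, Myl1 between 470 and 2006 against at most 253, and Mylpf between 355 and 601 against at most 307. The scaling of these arrays was argued against, as 5 of 5 column medians lay inside the range of the others. Muscle tissue in the liver sample is a candidate source, though Ckm, muscle creatine kinase, between 172 and 296, did not stand apart from the others at up to 272. No biological explanation was tested, since the arrays came from 4 groups.

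Lipogenesis genes averaged 0.46 ± 0.37 in MET relative to CON, whose SD was 0.06 (exact p = 0.0571, adjusted p = 0.0571). A single mouse as the cause was argued against, as 3 of 4 MET arrays lay above all CON arrays, although they spread from 0.03 to 0.93. Whether MET mice were less fasted than CON stayed open. The gluconeogenesis list was higher by 0.195 in MET, with 4 of 4 arrays above all CON arrays (exact p = 0.0286, adjusted p = 0.0571 over 3 tests), but 4 of 4 arrays were also above CON in SOY (mean 0.114), ROS (0.148), GM (0.223), CR8 (0.148) and LTCR (0.543), though in only 2 of 4 in GLIP (0.034), so CON may stand low on it, and Pck1 of that list had -0.28 ± 0.14 in MET (SE; adjusted p = 0.302). An effect of metformin may remain as a hypothesis beside a difference in fasting, with hybridization day not tested.

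An array was taken as far from the other 3 of its group where its gap to the nearest, as a share of the whole range, exceeded Dixon's 95% critical value, which chance gives in about 1 in 20 groups. This held in 20 of 330 sets of a gene and a group and in 16 of 264 sets of a list or quality measure and a group. CR8 3 was high for Irf7 (0.918), Cyp26a1 (0.832), the interferon list (0.847) and the lipogenesis list (0.907). GM 3 was high for Sec61b (0.949) and low for Gsta2 (0.842), Ndufb8 (0.852) and cholangiocyte markers (0.868). CON 4 was high for Zbtb16 (0.832) and Rpl19 (0.941) and low for the endoplasmic reticulum list (0.842). LTCR 3 was low for Rps18 (0.893) and Fads1 (0.890) and high for the endoplasmic reticulum list (0.856). GLIP 3 was low for the Gapdh 3' to 5' ratio (0.852) and high for the interferon list (0.918) and endothelial markers (0.947). GLIP 2 was high for Sdc4 (0.886) and Tpmt (0.904), and GLIP 1 for F12 (0.840). GM 2 was low for F12 (0.883) and Star (0.859), and GM 4 high for Psma7 (0.905). MET 3 was high for Rpl41 (0.892) and low for 18S intensity (0.867), and MET 1 was low for Brca2 (0.854). LTCR 4 was high for Acly (0.868) and LTCR 2 low for macrophage markers (0.844). CON 3 was high for Thrsp (0.951) and CR8 2 for Tbx3 (0.852). SOY 2 was low for the lipogenesis list (0.848) and high for acute phase genes (0.850), SOY 1 was low for the growth hormone, IGF and insulin list (0.885) and SOY 3 high for muscle markers (0.873). ROS 2 was low for lipoproteins (0.863) and ROS 1 for glycolysis (0.897).

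For Srebf1 the difference between glipizide and no glipizide with metformin, set against that without it, gave an interaction (GM minus MET, less GLIP minus CON) of -1.04 ± 0.18 (SE) on the log2 scale (limma adjusted p = 0.0116), of which GM minus MET was -0.93 ± 0.13. The call ended in some alternatives, given below. The control probe set for 18S ribosomal RNA, outside the gene tests, averaged 827 ± 256 intensity units in ROS (SD, n = 4), with 3 of 4 arrays above the highest CON array at 640 and ROS 1, at 467, below the lowest at 509, against 589 ± 60.5 in CON (exact p = 0.143, adjusted p = 0.320). In LTCR and CR8, at 362 ± 185 and 405 ± 158 (adjusted p = 0.3 for each), 3 of 4 arrays lay below the lowest CON array. Whether this bears on the changes there was not tested.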

How the results depend on the processing

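Fits without muscle-marked or acute-phase arrays, with SOY as reference, and of the interaction and genes chosen later were added after the data had been seen; the others were fixed beforehand. Of 165 named gene results past the threshold, 67 kept direction and call in every alternative fixed beforehand. Calls ended for 14 with quantile normalization, 11 with median scaling, 25 without a filter, 77 in fits to the 2 groups alone, 7 with the replicate block, 3 with an added value of 1, 51 without the muscle-marked arrays, 18 without the acute-phase arrays and 38 with SOY as reference. With each array left out in turn, 289 calls ended and 1031 did not. Of 54 named gene results not past the threshold, 1 passed with quantile normalization, 1 with median scaling, 3 in fits to the 2 groups alone, 1 with a filter at the 60th percentile, 1 with an added value at the 40th percentile, 1 without the acute-phase arrays and 4 with SOY as reference. With each array left out in turn, 7 passes were gained. The cause was not tested for any moved or reversed value below.

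Signs turned under quantile normalization for Apoa4 in LTCR (-0.032), Pck1 in GM (-0.0059) and Cyp4a12b in SOY (-0.021), and under median scaling for Pck1 (0.0050) and Dbp (0.035) in CR8. Without the muscle-marked arrays they turned for Fasn in LTCR (0.085), Igfbp1 in CR8 (0.25), Pdk4 (0.094) and Igfbp1 (0.0040) in MET, Pck1 in GM (-0.018) and Cyp4a12b in SOY (-0.030), and without the acute-phase arrays for Nsdhl in GM (-0.091) and Cd36 in ROS (0.042). With SOY as reference they turned for Pck1 (0.17) and Dbp (0.027) in CR8, Hspa5 (-0.049) and G6pc (-0.14) in GM, and Cd36 (0.058) and Rpl19 (-0.061) in ROS. None of these genes was past the threshold in these comparisons. Under quantile normalization the medians of the lipoprotein list in SOY (0.0022) and the oxidative phosphorylation list in GM against GLIP (0.017) stayed above 0, while camera's direction, set against the other genes, turned.

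Counts of calls moved with median scaling in GLIP (6, all 6 shared), GM (427, 82 shared) and GM against GLIP (1), without a filter in GLIP (6, 6 shared) and GM (57, 56 shared), and in fits to the groups compared alone in CR8 (16, 12 shared), MET (33, 28 shared), GM (4, 3 shared), ROS (5, 5 shared), LTCR against CR8 (488, 430 shared) and GM against MET (0 in limma, 1018 at unadjusted p under 0.05). Such fits hold fewer arrays. Without the muscle-marked arrays they were 29 in CR8 (13 shared), 95 in MET (89 shared), 2 in GLIP (2 shared), 33 in GM (28 shared) and 423 in LTCR against CR8 (366 shared), and without the acute-phase arrays 79 in GM against MET (74 shared). With SOY as reference they were 62 in CR8 (24 shared), 5 in GLIP (2 shared), 5 in GM (2 shared) and 34 in ROS (9 shared).

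Replicate numbers did not pair the arrays: deviations of arrays with the same number correlated at -0.01 on average. At most 2 of a first group's 4 arrays correlated best with their own number. With the replicate block limma called 4 in GLIP (4 shared), 1377 in LTCR, 40 in CR8, 284 in MET, 80 in GM, 10 in ROS, 0 in SOY (576 at unadjusted p under 0.05), 806 in LTCR against CR8, 182 in GM against MET and 0 in GM against GLIP (651 at unadjusted p under 0.05). Camera then called 97 lists, 94 of them shared.

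Of 96 list calls, 2 were made with an estimated correlation and 45 among the 61 of fry. Quantile normalization kept 66, median scaling 79, no filter 86, a filter at the 60th percentile 73 (19 ended), an added value of 1 95 and one at the 40th percentile 95. With single arrays left out the difference of the list means turned its sign in 4 of the 96 and kept its sign but fell over 1.5-fold in 27. The covariance with LTCR was 0.0377 for CR8 with an added value of 1, 0.0214 with one at the 40th percentile, 0.0188 without a filter and 0.0507 with shared controls, and for ROS 0.0148, 0.00882, 0.00694 and 0.0326, with 0.0141 at the stricter filter. Shared controls, which add covariance by construction, gave 0.0553 for MET, 0.0268 for GLIP, 0.0283 for GM and 0.0122 for SOY.

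Leaving out each array in turn gave between 1066 and 1523 calls in LTCR, 11 and 68 in CR8, 140 and 234 in MET, 1 and 11 in GLIP, 28 and 112 in GM, 4 and 12 in ROS, 0 and 1 in SOY, 572 and 949 in LTCR against CR8, 94 and 226 in GM against MET, and 0 and 2 in GM against GLIP. The covariance with LTCR (no CON array omitted) was 0.027 to 0.033 in CR8 and 0.024 to 0.042 in MET. In GLIP it was -0.0023 to 0.015, in GM 0.0035 to 0.012, in ROS 0.011 to 0.013 and in SOY -0.014 to -0.005. Log2 changes lay between -0.016 and 0.20 for Apoa4, -0.16 and 0.0075 for Cpt1a and -0.11 and 0.085 for Fasn in LTCR, -0.066 and 0.0091 for Dbp and -0.50 and 0.14 for Igfbp1 in CR8, -0.64 and 0.0040 for Igfbp1 and -0.61 and 0.094 for Pdk4 in MET, -0.19 and 0.10 for G6pc in GLIP, -0.11 and 0.33 for G6pc, -0.091 and 0.21 for Nsdhl and -0.018 and 0.10 for Pck1 in GM, and -0.15 and 0.10 for Cd36 and -0.041 and 0.96 for Pdk4 in ROS.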

Other observations

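Genes in the first paragraph and tests in the others, except the interaction regroupings, were chosen after values were seen. In LTCR against CON, 4 of 16 genes of circadian output rose and 2 fell (the same adjusted over the list alone). Cry1, a repressor of the clock, rose by 1.09 ± 0.26 (SE, n = 4), Arntl by 0.63 ± 0.22, Rora by 0.46 ± 0.14 and Clock by 0.36 ± 0.13, and Dbp fell by 1.17 ± 0.12 and Bhlhe40 by 0.58 ± 0.15. Of 9 class II genes of antigen-presenting cells, H2-Aa fell by 1.84 ± 0.39 and H2-Ab1 by 1.11 ± 0.31, the same 2 adjusted over the list alone. Pparg fell by 1.36 ± 0.27, Casp6 by 1.05 ± 0.17 and Ccng1, cyclin G1, by 0.89 ± 0.13. Of 42 proteasome genes, 8 fell (8 adjusted over the list alone), among them Psmd12 by 1.34 ± 0.31, Psmd14 by 0.79 ± 0.14 and the interferon-inducible Psmb9 by 1.10 ± 0.27 and Psmb8 by 0.94 ± 0.28. Of 22 genes of xenobiotic metabolism, 6 rose and 2 fell (7 and 3 adjusted over the list alone), with Cyp2c39 at 0.96 ± 0.11, Cyp2c38 at 0.74 ± 0.12 and Cyp2j5 at -1.17 ± 0.35. Camera called none of these 4 lists (adjusted p = 0.364, 0.180, 0.156 and 0.316; with an estimated correlation adjusted p = 0.596, 0.596, 0.747 and 0.83). Single arrays ended the calls of Arntl (adjusted p = 0.121 without CON 1), Clock (0.15 without CON 1), Rora (0.0985 without CON 4), H2-Ab1 (0.0597 without LTCR 2), Psmb8 (0.0649 without CON 4) and Cyp2j5 (0.0870 without LTCR 1), and no sign turned. Psmd12 stayed past the threshold without LTCR 4, at -0.84 ± 0.24. Neither other scaling ended a call, those of Arntl, Rora and Clock ended without the muscle-marked arrays, those of Arntl and Clock without a filter, those of Rora, Clock and Psmd12 in a fit to both groups alone, and those of Rora and Bhlhe40 with SOY as reference.

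Whether glipizide changes the lipogenic response to metformin was tested as an interaction. Limma called 3 probe sets, with 653 at unadjusted p under 0.05: Srebf1 at -1.04 ± 0.18 (SE), 1 probe set of Pklr at -1.71 ± 0.30, whose other had -0.71 ± 0.19 (adjusted p = 0.143), and 1 of Nmt1 at 0.57 ± 0.10, whose other had 0.13 ± 0.17 (adjusted p = 0.889). Of 100 regroupings of the 16 arrays, 4 gave as many calls, the real one included. The highest other gave 18, several times the real count, which may point to a structure of these arrays that was not tested. Limma called 0 in a fit to the 4 groups alone (571 at unadjusted p under 0.05) and 0 without the arrays with muscle transcripts (547), where fewer arrays entered and the sizes hardly moved: Srebf1 had -1.04 ± 0.17 (adjusted p = 0.0680) and -1.01 ± 0.19 (0.0571), and Nmt1 0.57 ± 0.11 (0.111) and 0.57 ± 0.11 (0.0584). It called 1 with median scaling, where Srebf1 had -0.99 ± 0.20 (adjusted p = 0.0508), 12 with quantile normalization, 10 with an added value at the 40th percentile, 8 with the stricter filter, 9 over probe sets of single transcripts, 6 with the replicate block, 11 without CON 2, 8 without GLIP 1, 20 without GLIP 3, 23 without MET 3 and 13 without MET 4, so the count depends on single arrays, although the 3 probe sets stayed called with each array left out. The lipogenesis list gave -0.49 (exact p = 0.0857, adjusted p = 0.129), with 4 of 4 GM arrays below all MET arrays, cholesterol synthesis -0.57 (0.118; 0.142), endoplasmic reticulum genes 0.30 (0.182; 0.182), the proteasome 0.17 (0.0498; 0.125), interferon genes 0.57 (0.0229; 0.125) and female-predominant genes -0.88 (0.0624; 0.125). None of the 6 passed after adjustment, and the hypothesis was neither excluded nor borne out.

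Cyp2b13, of the female-predominant list, and Sult2a2, a sulfotransferase, varied widely between mice of a group, at 2314 ± 1342 and 2489 ± 1553 intensity units in MET and 278 ± 223 and 260 ± 156 in GM (SD, n = 4). Their deviations from the group means, over 32 arrays, had Pearson's r = 0.803 (permutation p = 1e-05, the smallest that the 100000 resamples can give) and Spearman's rho = 0.783 (permutation p = 2e-05). Without the 2 arrays farthest from the median, r was 0.753 over 30. This was the 1 pair tested, chosen after both were seen to vary, and a shared regulator may act on both, a hypothesis not tested further.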
